A study of Mus musculus with 2 samples.

How the data were processed

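The series holds 2 droplet single-cell RNA-seq libraries of mouse tumours, 1 from mice fed a control diet and 1 from mice fed a diet with sitagliptin, an oral inhibitor of the peptidase DPP4 (CD26). The tumours were grown from MC38-OVA, a mouse colon carcinoma line that carries ovalbumin as a model antigen. Per the labels, cell suspensions of the tumours were enriched for CD45+ cells by magnetic sorting (MACS) and libraries were made with the SeekOne DD 5' kit. Groups were taken from the treatment label of each sample. How many mice went into each library is not given in the sources used here.

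The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode, with 32285 Ensembl gene IDs and their symbols, the same list in both libraries. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. The lowest total in both matrices was 2001 UMIs, so every barcode in the files exceeds 2000 UMIs, a floor set before deposit that can leave out small cells with little RNA. No cell annotation was used here, and cell classes were rebuilt from the counts.

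Counts were read with scanpy 1.11.5 and anndata 0.12.19 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Genes that share a symbol were summed. Barcodes needed at least 200 genes, at least 500 UMIs and at most 20% of UMIs in mitochondrial genes, and all barcodes passed. Doublets were scored per library with Scrublet as in scanpy (expected rate 0.06, seed 0). The automatic threshold marked 0% of barcodes in either library, so the 6% with the highest scores were removed, as had been fixed for that case. This took out 522 of 8694 control barcodes and 586 of 9766 sitagliptin barcodes, and left 8172 and 9180.

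Both libraries were clustered together without integration: 10000 counts per cell, log1p, 2000 variable genes without V, D and J segments, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0. T and NK cells and mononuclear phagocytes were clustered again with their own variable genes. The same step for dendritic cells was added after the data were seen. Clusters were named from marker lists fixed before the data were examined, needed at least 3 detected markers, and were checked for markers of other classes among their 10 leading genes by fold. Clusters that carried genes of different kinds of cells together, mostly T cell genes with macrophage genes, were kept out of every class as mixed barcodes, which was decided after the data were seen and without a fixed limit. The mixed clusters had between 210 and 1794 CPM of the macrophage gene C1qa, against at most 29.1 CPM in the T cell and NK cell clusters. The clusters of plasmacytoid dendritic cells (644 CPM) and plasma cells (212 CPM) were kept as classes despite similar levels, and so were neutrophils. Also kept out were 2 clusters of mixtures with low UMI counts, 2 clusters with little Ptprc (the gene for CD45) and 1 small cluster with osteoclast genes such as Ctsk and Acp5, for which no marker list had been fixed. A comparison within a class needed 100 cells in each library. T cells, NK cells, dendritic cells and the joint class of monocytes and macrophages met this. CD8 T cells outside the cycling cluster (99 control cells), CD4 T cells, regulatory T cells, B cells and neutrophils did not. CD8 T cells together with the cycling T cell cluster had 158 and 271 cells, but were not compared as a class.

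Class shares were given with exact Clopper-Pearson 95% intervals, and their ratio, sitagliptin over control, with a 95% log (Katz) interval. For expression, UMIs were summed per library and class and scaled to the class total as CPM, with exact Poisson 95% intervals. The ratio of CPM, sitagliptin over control, had the exact conditional binomial 95% interval. With 1 library per group there is no replicate error, so no test between diets was run, no p-value was computed and no number of changed genes was counted. All intervals of shares, ratios, levels and list medians cover counting error only. Where a class had 0 UMIs in 1 library, the ratio was computed against a floor of 3 counts in that class.

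The genes to be named were set by a rule written before the data were examined. For T cells, and for monocytes and macrophages, the 12 highest and 12 lowest ratios were taken among genes with at least 100 UMIs over both libraries and at least 50 CPM in the library where the gene was higher. For NK cells and dendritic cells, 5 per direction were taken. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, Gm, Rik, Xist, Tsix and Y-linked genes stayed out of the ranking. Dpp4 was read in every class.

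There were 20 gene lists fixed beforehand, each tied to certain classes. For each list the median log2 ratio was taken over members with at least 20 UMIs over both libraries, with a 95% counting interval from 500 binomial splits of each member's UMIs. The percentile of that median was read among 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression. Of the lists, 17 were run, giving 46 pairs of list and class. The lists of regulatory T cell genes, neutrophil activation genes and neutrophil maturity genes had no class with enough cells and were not run. The symbols Cxcl11, Mx1 and Mx2 were not analysed. Single values of a few list members are not reported here. For shares of cells with a UMI, each cell was thinned to 2000 UMIs, which left out no barcode. Shares of T cell receptor V segments were computed over the V segment UMIs of T cells, and their Shannon diversity after drawing the same number of cells from both libraries.

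The functions were tested on simulated counts for the real genes, with 200 genes changed by a known fold in each class. Counts per gene and class were drawn as Poisson counts, as the intervals assume, so the test leaves out the spread of UMIs between cells. The 95% intervals covered the true ratio for 95.8% of 3675 genes in T cells, 95.6% of 1915 in NK cells, 95.2% of 10544 in monocytes and macrophages and 95.3% of 2432 in dendritic cells. A 1.5-fold change, simulated for 67 genes per class, gave an interval that left out 1 for 82.1% of them in T cells, 71.6% in NK cells, 97.0% in monocytes and macrophages and 76.1% in dendritic cells. A 4-fold change, simulated for 71 genes per class, did so for 100% in each class.

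The alternatives fixed beforehand were a mitochondrial limit of 10%, a minimum of 500 genes, doublets kept, Leiden resolution 2.0, classes from marker UMIs in each cell without clustering, lymphoid or myeloid cells as denominator, CPM without mitochondrial, ribosomal protein and haemoglobin genes, median-of-ratios size factors, the same mix of clusters in both libraries, list members with at least 100 UMIs, thinned shares of cells in place of CPM, and cells in place of UMIs for V segments. Further alternatives were chosen after seeing the data: mixed barcodes counted as T cells, all kept barcodes as denominator, and random lists matched on transcript length as well as expression. Transcript lengths came from GENCODE mouse release 21, in which 32158 of the gene IDs were found and 127 were not. Figures were drawn with matplotlib 3.10.9.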

Results

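The immune infiltrate of MC38-OVA tumours was compared between mice on a control diet and mice on a sitagliptin diet, to describe which immune cells the tumours held under DPP4 inhibition and what these cells expressed. The control library had 8694 barcodes and 64139749 UMIs, with a median of 5074 UMIs and 1972.5 genes per barcode. The sitagliptin library had 9766 barcodes and 76788699 UMIs, with medians of 5158.5 UMIs and 1921 genes. Mitochondrial genes took a median of 0.519% and 0.556% of a barcode's UMIs, and ribosomal protein genes 14.2% and 13.1% of all UMIs. Each diet had 1 library, so the values below compare these 2 libraries and have no replicate check. Intervals cover counting error only, except for the Shannon index.

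Monocytes and macrophages made up most of the immune cells in both libraries, and T cells took a larger share in the sitagliptin library. Of the cells in named immune classes, 207 of 4009 (5.16%, 95% interval 4.50 to 5.89) were T cells in the control library and 397 of 5386 (7.37%, 6.69 to 8.10) in the sitagliptin library, a ratio of 1.43 (1.21 to 1.68). Neutrophils, read from S100a8, S100a9, Csf3r and related genes, were 70 cells (1.75%) against 44 (0.817%), a ratio of 0.468 (0.322 to 0.681). Their cluster also carried the macrophage gene C1qa at 736 and 773 CPM, against 1527 and 1174.5 in monocytes and macrophages. It may thus hold mixtures with macrophages, which were not separated. NK cells were 121 (3.02%) and 173 (3.21%), ratio 1.06 (0.847 to 1.34), and dendritic cells 142 (3.54%) and 194 (3.60%), ratio 1.02 (0.822 to 1.26). Monocytes and macrophages were 3444 (85.9%) and 4525 (84.0%), a ratio of 0.978 (0.961 to 0.995). Plasma cells with Jchain and Mzb1 were rare, with 4 cells and 19, and plasmacytoid dendritic cells numbered 21 and 34, with C1qa at 937 and 441 CPM.

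The libraries were MACS-enriched for CD45 and hold no barcode of 2000 UMIs or fewer. Cells with little RNA of any class, small lymphocytes and neutrophils included, can thus be missing from these shares. The T cell ratio turned to 0.815 (0.754 to 0.881) when barcodes that carried T cell genes together with macrophage genes were counted as T cells, an alternative chosen after seeing the data, and over lymphoid cells it was 1.08 (0.977 to 1.20). All mixed barcodes, including those with dendritic cell genes and other mixtures, were 12.1% of the kept barcodes in the control library and 8.65% in the sitagliptin library. Low-UMI mixtures outside any class were 20.3% and 22.6% of kept barcodes. They lay in 2 clusters, one with 1469 control and 331 sitagliptin barcodes and the other with 193 and 1741, so each may be a library rather than a cell type. Cells with little Ptprc were 18.3% and 9.98%, and the cluster with osteoclast genes held 16 and 12 cells. The ratio for monocytes and macrophages was 1.01 over myeloid cells, 1.05 with mixed barcodes counted as T cells and 1.17 over all kept barcodes. That of NK cells lay below 1 over lymphoid cells (0.806) and with classes from marker UMIs (0.823). Over all kept barcodes the NK cell ratio was 1.27 (1.01 to 1.60).

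**Figure D1:**
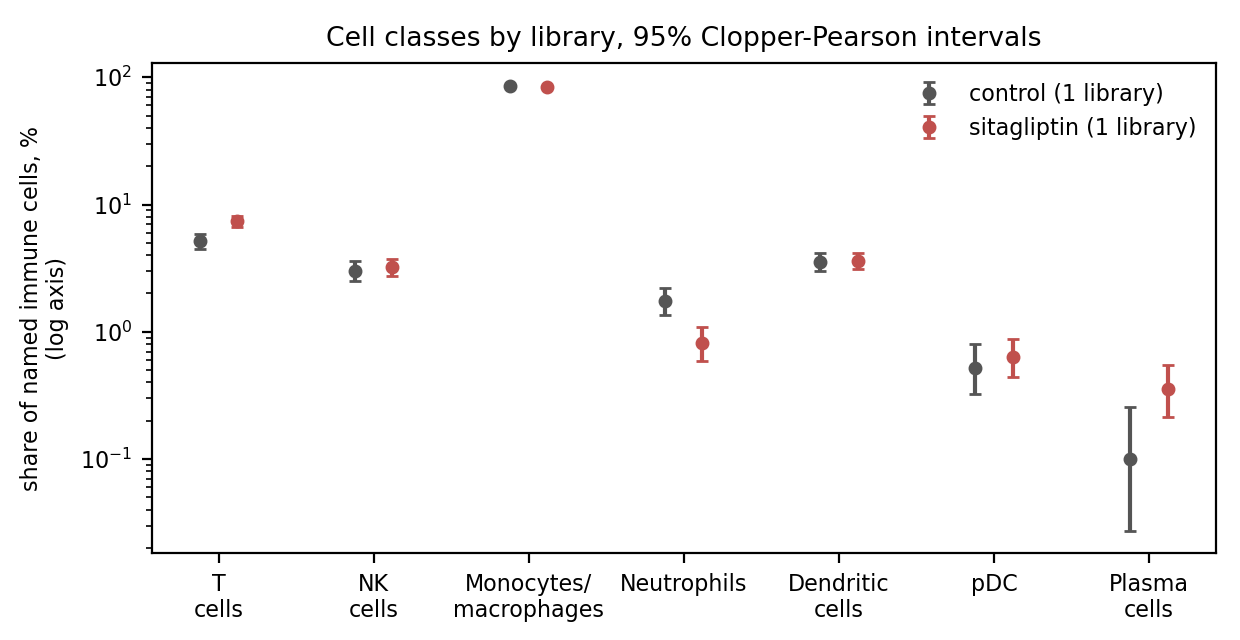
Share of named immune cells (percent, log axis) for each cell class in the control library (grey) and the sitagliptin library (red), with exact 95% Clopper-Pearson intervals for counting error as bars. T cells stand at 5.16% and 7.37%, neutrophils at 1.75% and 0.817%, and the intervals of NK cells, dendritic cells and plasmacytoid dendritic cells (pDC) overlap.

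Within the T cells, the cluster of CD8 T cells with Cd8a and Cd8b1, outside the cycling cluster, made up 47.8% in the control library and 51.4% in the sitagliptin library. With the cycling T cell cluster, which also expressed Cd8a, the shares were 76.3% and 68.3%, a ratio of 0.894 (0.808 to 0.990). The cycling cluster had 332 CPM of Cd3e, against 9.94 in the NK cell cluster. Its level of the NK cell gene Ncr1 was 22.7 CPM, against 0 to 10.1 in the other T cell clusters and 114 in the NK cell cluster. It may thus hold some NK cells, which were not separated. Regulatory T cells with Foxp3 and Il2ra were 16 cells (7.73%) and 21 cells (5.29%), a ratio of 0.684 (0.365 to 1.28). The T cell gene Cd3e had 298 and 489 CPM in T cells (1.64, 1.42 to 1.90), whereas Cd3d, Cd3g, Trac and Trbc2 had ratios of 0.948 to 0.984 with intervals that included 1. Cd8a was lower (0.791, 0.702 to 0.893) and Cd8b1 higher (1.32, 1.14 to 1.52), all named here after their values were seen. Among monocytes and macrophages, the monocyte-like clusters with Plac8, Vcan and Ly6c2 held 14.9% (13.7 to 16.1) of control cells and 18.5% (17.4 to 19.7) of sitagliptin cells. Among dendritic cells, cDC1-like cells with Xcr1 and Clec9a were 11.3% and 14.4% (ratio 1.28, 0.721 to 2.28). Those of cDC2 type with Cd209a and Clec10a were 35.9% and 43.3% (ratio 1.21, 0.918 to 1.58). Both intervals included 1.

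Dpp4, the target of sitagliptin, was read mainly in dendritic cells and T cells. In dendritic cells it had 150 CPM in the control library and 167 CPM in the sitagliptin library, a ratio of 1.11 (0.843 to 1.47). In T cells it had 68.0 and 85.1 CPM, a ratio of 1.25 (0.908 to 1.75). Neither difference was detectable at this depth. Monocytes and macrophages had 4.78 and 3.18 CPM, a ratio of 0.665 (0.505 to 0.877). With each cell thinned to 2000 UMIs, a Dpp4 UMI was seen in 26.8% and 22.2% of dendritic cells and in 12.6% and 15.1% of T cells, without thinning in 39.4% and 49.0% and in 20.8% and 23.9%. The thinned ratio for dendritic cells was thus 0.828, on the other side of 1 from their CPM, and no order was read from it. The thinned share was 1.19% and 0.729% in monocytes and macrophages (median depths 5354 and 6501 UMIs) and 0.0668% and 0.109% in cells with little Ptprc (13929 and 18798 UMIs), against median depths of 3183 and 3157 in T cells and 3196 and 4711.5 in dendritic cells. NK cells had 1 and 4 Dpp4 UMIs.

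The list of the DPP4 family with the chemokines that DPP4 cleaves and their receptors had a median log2 ratio of 0.24 in T cells (6 members higher, 5 lower, percentile 98.7 among 10000 matched random lists, and 0.040 with the same mix of clusters in both libraries), 0.18 in dendritic cells (8 and 3, percentile 98.1), 0.11 in NK cells (4 and 3, percentile 79.0, and 0.45 over members with at least 100 UMIs) and −0.10 in monocytes and macrophages (4 and 11, percentile 30.03), where it was −0.018 with the same mix. In monocytes and macrophages Cxcl9, an interferon-induced T cell attractant and DPP4 substrate, had 445 CPM in the control library and 569 CPM in the sitagliptin library, a ratio of 1.28 (1.25 to 1.31), and Cxcl10 271 and 302 CPM. The share of these cells with a Cxcl9 UMI after thinning was 27.2% and 28.4%, a ratio of 1.04. In dendritic cells the chemokine gene Ccl4 had 74.2 and 216 CPM, a ratio of 2.92 (2.07 to 4.21), while Ccl5 was lower at 1277 and 1034 CPM. The share of dendritic cells with a Ccl4 UMI after thinning had a ratio of only 1.24. Cxcl2 (108 and 203 CPM) and Cxcl10 (34.6 and 58.9 CPM) were higher in T cells by CPM but had ratios of 0.842 and 0.695 in thinned shares of cells, and Cxcl2 was at 5145 and 4934 CPM in monocytes and macrophages.

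T cells of the sitagliptin library had lower levels of granule and effector genes, cell cycle genes and glycolysis genes, and higher levels of interferon-induced and memory-associated genes. This class held 207 control and 397 sitagliptin barcodes, against 1020 and 1039 when barcodes with T cell and macrophage genes together were counted in. The levels thus cover a smaller part of such barcodes in the control library. Whether this selection bears on the levels was not tested. Of the 18 cytotoxic effector genes, 14 were lower and 4 higher, with a median log2 ratio of −0.38 (95% counting interval −0.51 to −0.23) at percentile 0.02. With the same mix of clusters in both libraries the median was −0.26. Gzmb, the granzyme that triggers apoptosis in target cells, had 4057 CPM in the control library and 2552 CPM in the sitagliptin library, a ratio of 0.629 (0.601 to 0.659). Prf1, which encodes the pore protein perforin, had 292 and 152 CPM (0.520, 0.432 to 0.625). Against this direction, Ifng, the gene for interferon gamma, had 71.7 and 117 CPM, a ratio of 1.63 (1.21 to 2.23). Among genes of inhibitory receptors and exhaustion, 12 of 14 measured members were lower (median −0.28, percentile 0.81). With random lists matched also on transcript length, an alternative chosen after seeing the data, this list lay at percentile 2.64, within the central 95%. Pdcd1, the gene for PD-1, had 184 and 141 CPM (0.764, 0.618 to 0.947), and Ctla4, a checkpoint receptor, 347 and 249 CPM (0.717, 0.613 to 0.838). Tox, a transcription factor of exhausted cells, had 116 and 134 CPM.

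Naive and memory T cell genes had 9 of 10 members higher in the sitagliptin T cells, with a median log2 ratio of 0.26 at percentile 99.3, and 0.17 with the same mix of clusters in both libraries. Il7r, the receptor chain for the survival cytokine IL-7, had 194 and 238 CPM (1.23, 1.015 to 1.49), and S1pr1, which guides lymphocytes out of tissue, 16.1 and 33.3 CPM (2.07, 1.11 to 4.14). Type I interferon response genes had 16 of 17 measured members higher (median 0.43, percentile 100, and 0.24 over members with at least 100 UMIs), led by Ifit3, an antiviral effector, at 12.4 and 51.2 CPM (4.14, 2.14 to 8.96). Xaf1 had 23.5 and 47.3 CPM (2.02, 1.20 to 3.54), and Isg20 was the member that was lower (0.684). The interferon gamma response list had 8 members higher and 10 lower (median −0.04, and 0.041 with the same mix of clusters), and MHC class I genes 2 and 9 (median −0.11, percentile 38.8). In monocytes and macrophages the type I interferon list was divided, with 13 members higher and 11 lower.

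Cell cycle genes were lower in sitagliptin T cells for 20 of 24 members (median −0.44, percentile 0). Cdk1, the kinase that drives entry into mitosis, had 58.1 and 21.8 CPM (0.374, 0.234 to 0.595), and Mki67 491 and 337 CPM (0.686, 0.601 to 0.783). The cluster of cycling T cells held 28.5% of control and 16.9% of sitagliptin T cells, and with the same mix of clusters in both libraries the median was −0.11. Glycolysis and hypoxia genes were lower for 15 of 18 members (median −0.42, percentile 0, and −0.32 with the same mix of clusters), among them the glycolytic enzyme Aldoa at 593 and 299 CPM (0.505, 0.443 to 0.574). The remaining lists in T cells were those of oxidative phosphorylation (median −0.18, percentile 10.9), NRF2 target genes (−0.25, percentile 10.1) and dissociation stress and immediate early genes (−0.26, percentile 1.72). Of genes abundant in macrophages, Lyz2 (187 and 85.7 CPM) and Spp1 (299 and 138 CPM) were also lower in the sitagliptin T cells. C1qa was at 25.96 and 23.7 CPM. Spp1 had 1054 and 744 CPM in NK cells but 68.5 and 79.3 CPM in dendritic cells, so its source in T cells was not settled.

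Of the single genes in T cells, Zbed5 stood first among those higher in the sitagliptin library. Zbed5, a gene derived from a DNA transposase, had 0 UMIs in control T cells and 161 in sitagliptin T cells. Against the floor of 3 counts its ratio was 27.8, and its counting interval began at 22.3. Cdk8, the kinase of the Mediator complex, had 1289 and 2708 CPM (2.10, 1.963 to 2.25), and Atp5k, a subunit of ATP synthase, 85.3 and 196 CPM (2.30, 1.76 to 3.03). The interferon-inducible GTPase gene Tgtp2 (1.93) and Tagap (1.98) were also among the 12 highest, with Scml4, Slco3a1, Cetn2, Crnkl1, Mfsd6, Tmem56 and Cxcl2 at ratios between 1.89 and 2.56. Among the 12 lowest were the granzymes Gzmc at 2761 and 1282 CPM (0.464, 0.437 to 0.493) and Gzmg (0.459), the chemokine Ccl4 at 383 and 175 CPM (0.456, 0.386 to 0.538), and the endoplasmic reticulum stress gene Creld2 (0.411). Fcer1g (0.440), Lyz2 (0.459) and Spp1 (0.460), all abundant in macrophages, were in the same group, and with doublet calls kept Lyz2 was at 0.641 and Spp1 at 0.690. The others were Ssr2, Serpine2, H2afx, Abhd17b and Pgp, with ratios of 0.438 to 0.473. With the same mix of clusters in both libraries Gzmc was at 0.581 and Gzmg at 0.317, and with doublet calls kept Gzmc was at 0.429. The share of T cells with a Ccl4 UMI after thinning had a ratio of only 0.756.

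**Figure D2:**
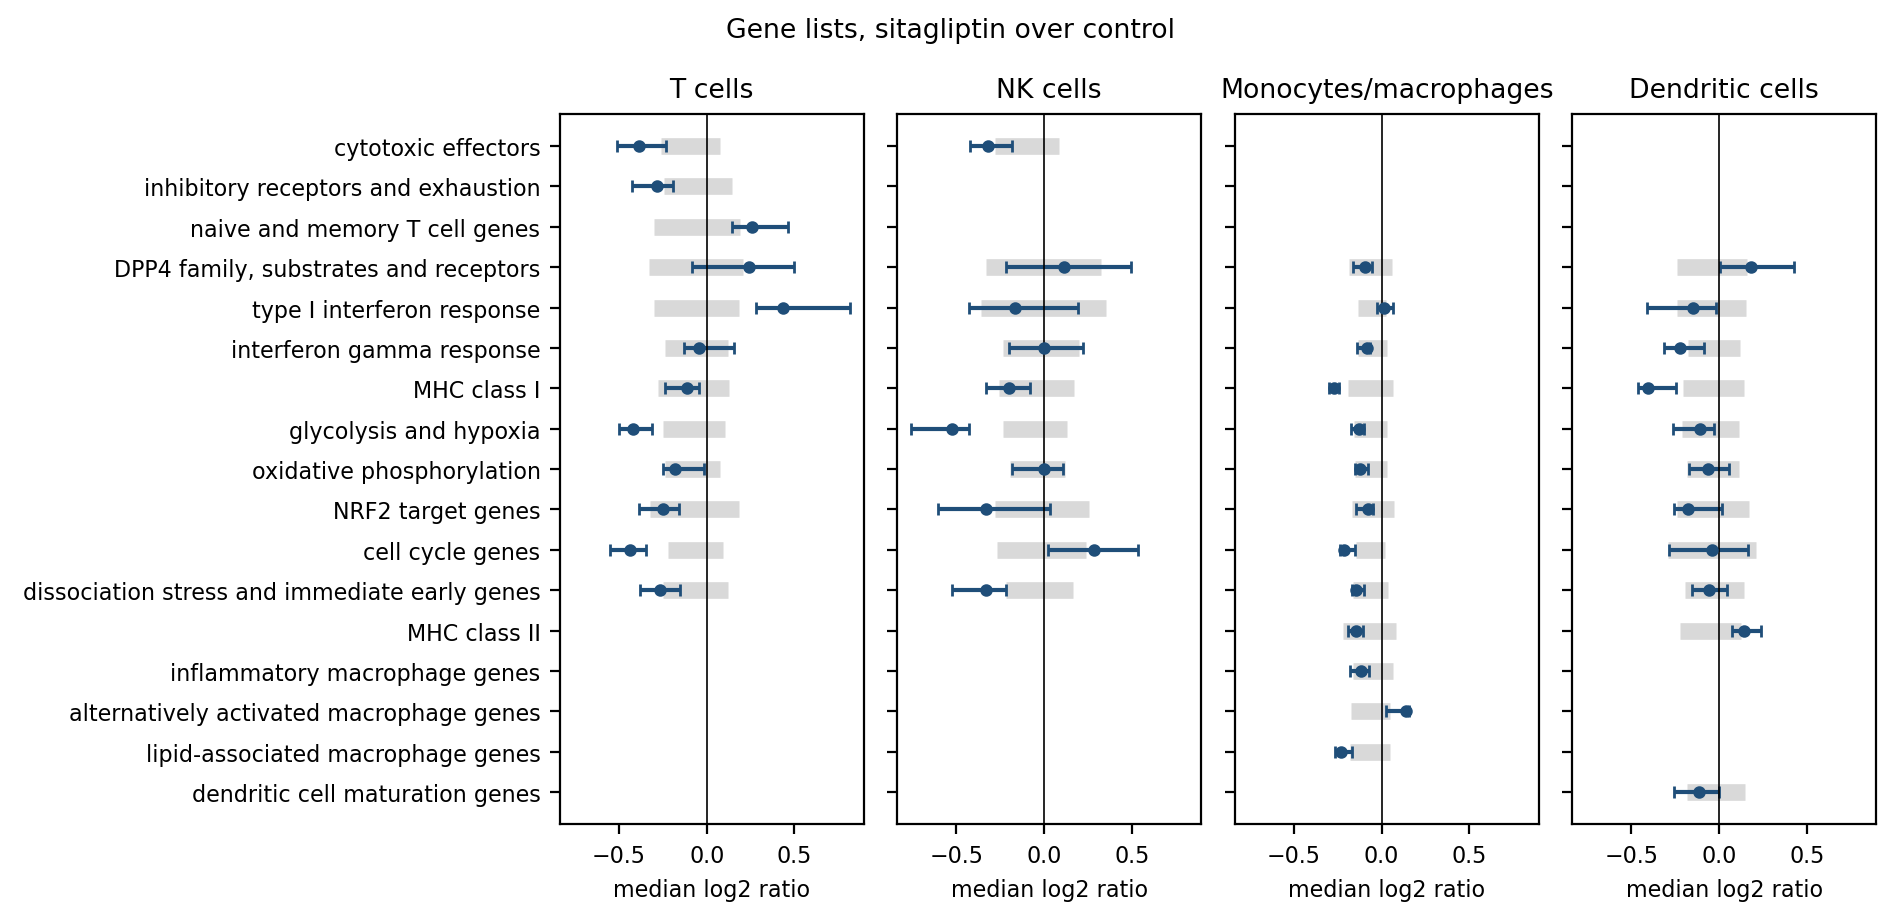
Median log2 ratio of CPM, sitagliptin over control, of each fixed gene list in T cells, NK cells, monocytes and macrophages, and dendritic cells (points, with 95% counting intervals as bars), and the central 95% of 10000 random lists matched on expression (grey). In T cells the cytotoxic, glycolysis and cell cycle lists lie at −0.38, −0.42 and −0.44, and the type I interferon list at 0.43.

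NK cells of the sitagliptin library also had lower cytotoxic effector and glycolysis genes, while their cell cycle genes were higher. Cytotoxic effector genes were lower for 12 of 15 measured members (median log2 ratio −0.32, percentile 0.39). Gzmb had 5208 CPM in the control library and 3883 CPM in the sitagliptin library (0.746, 0.706 to 0.787), Prf1 700 and 475 CPM (0.679, 0.583 to 0.792), and Ifng 80.1 and 28.7 CPM (0.358, 0.200 to 0.626). Gzmf (1.32, 1.20 to 1.46) and Ccl5 (1.37, 1.17 to 1.60) were higher. Of the glycolysis and hypoxia genes, 15 of 17 were lower (median −0.53, percentile 0), led by Ero1l, a hypoxia-induced oxidase of the endoplasmic reticulum, at 371 and 115 CPM (0.309, 0.2355 to 0.403). Dissociation stress and immediate early genes were lower for 16 of 16 (median −0.33, percentile 0.09), among them Fos (0.529) and Egr1 (0.108). Cell cycle genes were higher for 13 of 16 (median 0.29, percentile 98.8, and 0.44 over members with at least 100 UMIs), with Hmgb2 at 379 and 561 CPM (1.48, 1.24 to 1.77).

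The remaining lists in NK cells were those of MHC class I (10 of 11 lower, median −0.20, percentile 8.10), NRF2 targets (−0.33, percentile 1.48), the type I interferon response (−0.16, percentile 22.01), the interferon gamma response (0.00, percentile 56.5, and −0.12 over members with at least 100 UMIs) and oxidative phosphorylation (0.00, percentile 69.9). By the rule for single genes, Nudcd3 (2.39), Txndc17 (2.22), Klra8, which encodes the activating receptor Ly49H (2.07), Pdcd4 (2.06) and AY036118 (2.01) were highest. Ero1l, Lgals3, the gene for galectin 3 (0.361), the metallothionein gene Mt1 (0.429), Sema4d (0.527) and Fos were lowest. Spp1, abundant in macrophages, was at 1054 and 744 CPM in the NK cells, and C1qa at 18.97 and 17.7 CPM, whereas Lyz2 had 52.7 and 77.8 CPM and Apoe 18.97 and 36.9 CPM.

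Monocytes and macrophages of the sitagliptin library had lower MHC class I, lipid-associated and cell cycle genes and higher levels of several genes of alternative activation. MHC class I genes were lower for 11 of 11 members (median log2 ratio −0.27, −0.30 to −0.24, percentile 0.02). H2-D1, a class I heavy chain, had 1710 CPM in the control library and 1340 CPM in the sitagliptin library (0.784, 0.773 to 0.794), and Psmb8, an immunoproteasome subunit, 483 and 388 CPM (0.804, 0.784 to 0.825). Lipid-associated macrophage genes were lower for 12 of 15 (median −0.23, percentile 0.11). Spp1, the gene for osteopontin, had 3706 and 2556 CPM (0.690, 0.683 to 0.696), and Trem2, a lipid-sensing receptor, 244 and 202 CPM (0.827, 0.798 to 0.857), whereas the lipase gene Lpl was higher (1.31, 1.17 to 1.46). Cell cycle genes were lower for 21 of 24 (median −0.22, percentile 0), and the cluster of cycling macrophages held 10.3% of control and 8.73% of sitagliptin cells of this class. With the same mix of clusters in both libraries, the median was −0.13 for cell cycle genes and −0.15 for lipid-associated genes.

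Alternatively activated macrophage genes were higher for 8 of 14 members in this class (median 0.14, 0.03 to 0.16, percentile 99.96). Tgfb1, which encodes an immunosuppressive cytokine, had 229 and 314 CPM (1.37, 1.32 to 1.42), Retnla 88.4 and 129 CPM (1.46, 1.38 to 1.54), and the mannose receptor gene Mrc1 616 and 715 CPM (1.16, 1.14 to 1.19). Arg1, the arginase that depletes arginine, was lower at 2833 and 2652 CPM (0.936, 0.926 to 0.945). The cluster led by Retnla, Ear2 and Lyz1 held 3.16% of control and 5.57% of sitagliptin cells of this class, and that with Mrc1, Ms4a7 and Folr2 15.7% and 19.3%. With the same mix of clusters in both libraries, the median of this list was 0.021, and over members with at least 100 UMIs 0.060. MHC class II genes were lower for 9 of 10 (median −0.15, percentile 17.4), among them Cd74 at 9578 and 7925 CPM. Inflammatory macrophage genes were lower for 11 of 14 (median −0.12, percentile 11.9), with Il1b at 3381 and 2956 CPM (0.874, 0.866 to 0.883).

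The median log2 ratio of all measured genes was −0.053 in monocytes and macrophages, −0.057 in T cells, −0.041 in dendritic cells and −0.021 in NK cells, and size factors moved every list median up by that amount. In monocytes and macrophages this gave −0.076 for glycolysis and hypoxia, −0.073 for oxidative phosphorylation, −0.027 for NRF2 targets, −0.033 for the interferon gamma response, −0.067 for inflammatory genes and −0.095 for MHC class II. The other lists in monocytes and macrophages were those of the type I interferon response (median 0.01, percentile 95.2, and −0.09 with the same mix of clusters), the interferon gamma response (−0.09, percentile 28.2, and −0.011 with the same mix), glycolysis and hypoxia (−0.13, percentile 9.57), oxidative phosphorylation (−0.13, percentile 8.53), NRF2 targets (−0.08, percentile 38.2) and dissociation stress and immediate early genes (−0.15, percentile 4.63).

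Among single genes in monocytes and macrophages, Zbed5 (ENSMUSG00000034173) again stood first. It had 16 UMIs (0.722 CPM) in the control library and 4161 (119 CPM) in the sitagliptin library, 165-fold higher (102 to 289). Cdk8 had 918 and 1839 CPM (2.004, 1.97 to 2.04). Also higher were Atp5k (1.93, 1.83 to 2.04), Pet100, an assembly factor of cytochrome c oxidase (1.78, 1.62 to 1.95), and Ndufb1-ps, named as a pseudogene of a complex I subunit (1.83, 1.75 to 1.91). The first enzyme of glycolysis, Hk2, had 54.2 and 84.8 CPM (1.56, 1.46 to 1.67), and Il31ra, a receptor chain for IL-31, 122 and 189 CPM (1.55, 1.48 to 1.62). The scavenger receptor-like gene Fcrls (1.75), Polr2l, Afg3l1, Tmem56 and Eif3j1 made up the rest, with ratios of 1.52 to 1.75. Lowest was the interferon-induced Ifitm1 at 247 and 152 CPM (0.615, 0.592 to 0.639), followed by Smap1 (0.676), Spp1 and the endoplasmic reticulum stress genes Creld2 (0.693) and Sdf2l1 (0.720). Klf2, Cfp (the complement factor properdin), Ucp2, Upp1, Glrx, Plk3 and Tle5 had ratios between 0.700 and 0.728. In the cells with little Ptprc, 12 of the 12 higher genes and 7 of the 12 lower genes lay on the same side of 1 with intervals that left out 1. Of these, Fcrls had only 34 and 46 UMIs there (1.57 and 2.62 CPM, against 41.5 and 72.6 in monocytes and macrophages). Its ratio there may come from free RNA of macrophages, which was not tested. In monocytes and macrophages its ratio was 1.44 with the same mix of clusters.

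**Figure D3:**
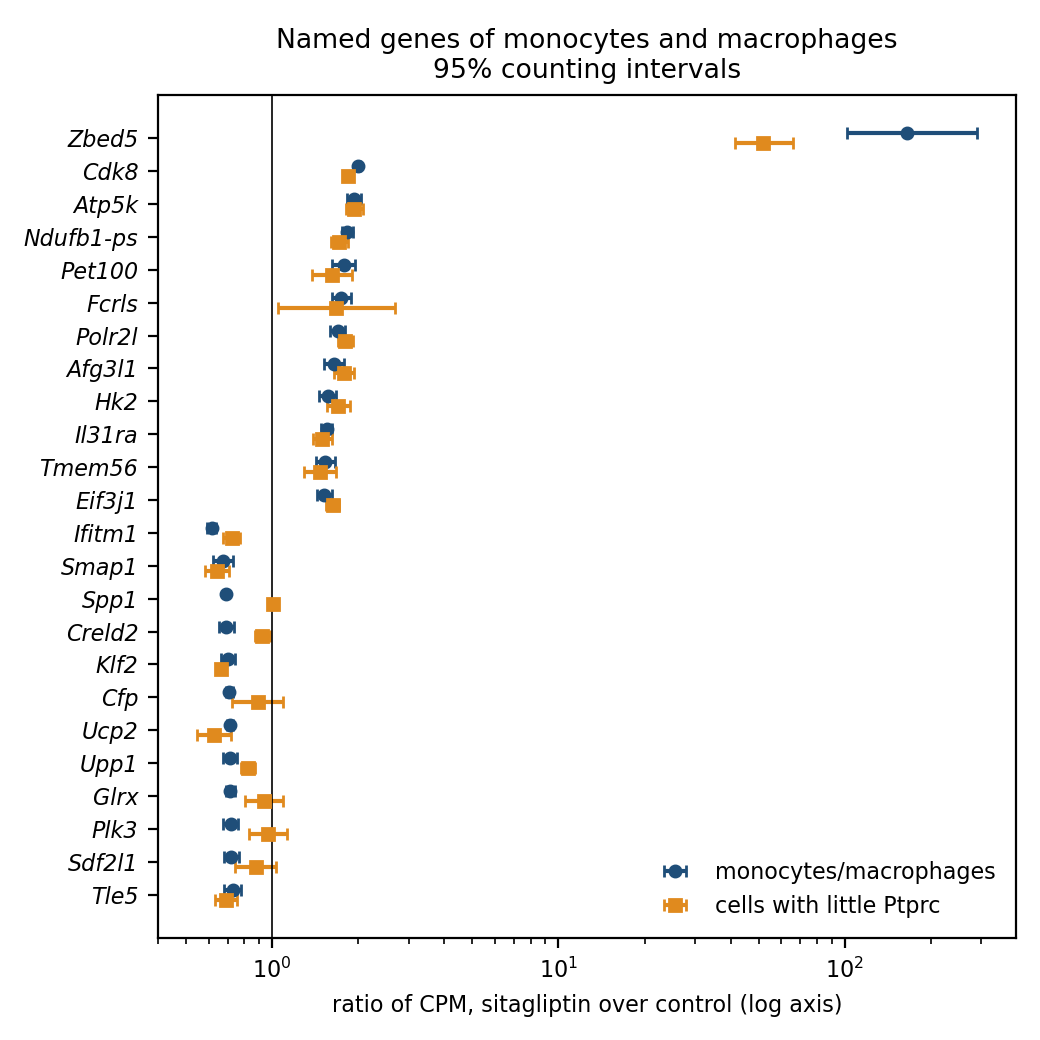
Ratio of CPM, sitagliptin over control (log axis), with 95% counting intervals, of the 12 genes with the highest and the 12 with the lowest ratio in monocytes and macrophages (blue), and of the same genes in cells with little Ptprc (orange). Zbed5 lies at 165 and 51.8, and all 12 higher genes lie above 1 in both kinds of cells, Fcrls from only 34 and 46 UMIs in those with little Ptprc.

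Dendritic cells of the sitagliptin library had lower MHC class I and interferon gamma response genes and higher MHC class II genes. MHC class I genes were lower for 11 of 11 members (median log2 ratio −0.40, −0.46 to −0.24, percentile 0, and −0.26 with the same mix of clusters). Psmb9, an immunoproteasome subunit, had 744 CPM in the control library and 503 CPM in the sitagliptin library (0.677, 0.592 to 0.774), and Tap1, which carries peptides to class I molecules, 379 and 279 CPM (0.737, 0.613 to 0.888). Of the interferon gamma response genes, 14 of 19 were lower (median −0.22, percentile 0.85), while the interferon-induced GTPase gene Iigp1 was higher (2.26, 1.43 to 3.73). MHC class II genes were higher for 8 of 10 (median 0.14, percentile 98.3), among them H2-Ab1 at 2720 and 3337 CPM (1.23, 1.15 to 1.31), and their median was 0.072 with the same mix of clusters and 0.075 with doublet calls kept.

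Maturation genes of dendritic cells went both ways. Ccr7, the receptor for migration to lymph nodes, had 862 and 512 CPM (0.594, 0.523 to 0.675), and Fscn1, an actin-bundling gene of mature dendritic cells, 533 and 284 CPM (0.533, 0.451 to 0.630), while the chemokine gene Ccl17 was higher at 679 and 1175 CPM (1.73, 1.54 to 1.95). The median of the list was −0.12 (5 members higher, 9 lower, percentile 12.7). Mature dendritic cells were 51 of 142 in the control library and 52 of 194 in the sitagliptin library, and with the same mix of clusters the median was 0.01. The other lists in dendritic cells were those of the type I interferon response (−0.15, percentile 15.3, and −0.40 with doublet calls kept), glycolysis and hypoxia (−0.11, percentile 21.97), oxidative phosphorylation (−0.06, percentile 39.3), NRF2 targets (−0.18, percentile 9.94), cell cycle genes (−0.04, percentile 50.2, and 0.014 over members with at least 100 UMIs) and dissociation stress and immediate early genes (−0.06, percentile 35.9, and −0.15 with the same mix of clusters). NRF2 targets were at −0.029 with doublet calls kept and at −0.32 over members with at least 100 UMIs.

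Single genes in dendritic cells were led by Zbed5, with 0 UMIs in the control library and 114 in the sitagliptin library. Against the floor of 3 counts its ratio was 19.6, and its counting interval began at 15.65. Next were Ccl4, the histone gene Hist1h2ae (2.72, 1.63 to 4.78), Rgs2, a regulator of G protein signalling (2.42, 1.75 to 3.40), and Rsl1d1 (2.36, 1.42 to 4.10). Batf3, the transcription factor needed for cDC1 development, was lowest at 122 and 45.1 CPM (0.370, 0.248 to 0.549). It was followed by the interferon-induced gene Oasl2 (0.397, 0.265 to 0.590), Hcfc1r1 (0.445), Spint2 (0.453) and Ppp4c (0.493).

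The 5' reads of T cells also covered the V segments of T cell receptor genes, with 454 Trbv UMIs in the control library and 701 in the sitagliptin library, found in 65.2% and 59.2% of T cells. The diversity of Trbv segments was alike, with a Shannon index of 2.60 in the control library and 2.61 (2.52 to 2.69) in the sitagliptin library at the same number of cells. That of Trav segments, from 137 and 211 UMIs, was 3.27 and 3.23 (3.06 to 3.37). By UMIs, several of which can come from 1 cell, single segments differed between the libraries. Trbv13-3 took 8.37% (5.99 to 11.3) of Trbv UMIs in the control library and 1.71% (0.888 to 2.97) in the sitagliptin library, Trbv29 1.54% and 6.56%, a ratio of 4.26 (1.94 to 9.34), and Trbv17 1 UMI (0.220%) and 42 UMIs (5.99%). By cells, Trbv13-3 was found in 13 and 6 (ratio 0.241, 0.0928 to 0.624), Trbv29 in 3 and 17 (2.95, 0.876 to 9.97) and Trbv17 in 1 and 11 (5.74, 0.746 to 44.1), so the last 2 were not detectable as differences in cells. Trbv15 took 7.27% and 2.28% of UMIs, but 3 and 7 cells carried it, a ratio of 1.22 by cells.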

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

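Counting mixed barcodes as T cells and using all kept barcodes as denominator were tests chosen only after the results were seen. So was matching random lists on transcript length. All others were fixed beforehand, but the same mix of clusters in dendritic cells rests on sub-clusters added after the data were seen. No paired analysis was possible because each group has 1 library and no result comes from a test. For shares, a 10% mitochondrial limit, a minimum of 500 genes, kept doublets and Leiden resolution 2.0 left all 5 class ratios within their intervals. The T cell ratio of 1.43 was 1.08 (0.977 to 1.20) over lymphoid cells, 1.71 over all kept barcodes and 0.815 with mixed barcodes as T cells. That of NK cells was 0.806 over lymphoid cells, 0.823 with classes from marker UMIs and 1.27 (1.01 to 1.60) over all kept barcodes. That of monocytes and macrophages was 0.996 with marker UMIs, 1.01 over myeloid cells, 1.17 over all kept barcodes and 1.05 with mixed barcodes as T cells. The new denominators and the moved barcodes give these differences by construction, except those with marker UMIs, where the cause was not tested.

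Leaving mitochondrial, ribosomal protein and haemoglobin genes out of CPM, and the 10% mitochondrial limit, moved none of the 68 named gene ratios or 46 list medians beyond their counting intervals. No named gene ratio changed sides under these, size factors, kept doublets or the same mix of clusters, while Cxcl2 in T cells did in thinned shares of cells (0.842). Size factors moved 5, kept doublets 4 and the same mix of clusters 9 of the 68. Of the 46 list medians, 11 moved with size factors, 11 with the same mix and 2 with members of at least 100 UMIs, and none moved with kept doublets. With size factors, the MHC class I median in monocytes and macrophages was −0.22 and that of alternative activation 0.19. With the same mix of clusters, these were −0.23 and 0.021, lipid-associated genes −0.15, and cell cycle genes −0.13 there and −0.11 in T cells. With members of at least 100 UMIs, the type I interferon median in T cells was 0.24, from fewer members. Size factors set the median of all genes to 0 by construction, and for the same mix the cause was not tested. Random lists matched on length left 42 of 46 percentiles on the same side of the limits of the central 95%. Exhaustion genes in T cells lay at 2.64, immediate early genes in T cells at 4.03, NRF2 targets in NK cells at 3.18 and the type I interferon list in monocytes and macrophages at 98.0.

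Thinned shares of cells in place of CPM moved 10 of 44 ratios of Dpp4 and its substrates and reversed 2, Cxcl2 and Cxcl10 (0.695) in T cells. Dpp4 in dendritic cells was 0.828. By cells in place of UMIs, 2 of 19 V segments moved and Trbv15 reversed to 1.22, with 33 and 16 UMIs in 3 and 7 cells. For the others the cause was not tested. Depth limited the NK cells most, with 474474 and 732447 UMIs in all.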

Other observations

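The lists in cells with little Ptprc, the trend with transcript length within each class, and the readings of mixed barcodes, of the spread of Zbed5 over cell classes, of Xist and of the tumour and epithelial list were tests chosen only after the results were seen, and the tests of UMI counts, transcript length and shared sequence were set before. Cells with little Ptprc (42.8 CPM in the control library and 34.1 in the sitagliptin library, against 688 and 700 in monocytes and macrophages) had large UMI totals, a median of 13929 and 18798. Of the 7 genes of the fixed fibroblast list, Dcn had 176 and 210 CPM, Col3a1 68.7 and 94.5 CPM and Col1a2 46.3 and 52.8 CPM, while Pdgfra (18 and 16 CPM), Pdgfrb (5.17 and 4.95 CPM), Col1a1 (2.26 and 7.80 CPM) and Lum (0 and 13 UMIs) were lower. The proliferation gene Mki67 had 277 and 274 CPM. In these cells the sitagliptin library had lower levels of the type I interferon list (23 of 24 members lower, median log2 ratio −0.53, percentile 0), the interferon gamma list (22 of 22 lower, −0.63, percentile 0) and MHC class I genes (10 of 11 lower, −0.53, percentile 0). T cells had the type I interferon list higher (0.43) in the same library. Glycolysis genes (−0.07, percentile 18.9) and immediate early genes (−0.06, percentile 27.2) stayed near the random lists in the cells with little Ptprc, and cell cycle genes lay at −0.12 (percentile 1.02). The lists of oxidative phosphorylation (−0.08), NRF2 targets (−0.03) and the DPP4 family (−0.16) lay at percentiles 11.1, 55.9 and 4.53.

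Across coding genes, those with short transcripts had lower ratios in the sitagliptin library. The shortest 10% by longest annotated transcript had a median log2 ratio of −0.22 in T cells, −0.11 in NK cells, −0.14 in monocytes and macrophages, −0.09 in dendritic cells and −0.10 in cells with little Ptprc. The other coding genes had −0.03, −0.02, −0.06, −0.04 and −0.02. Spearman's rho across genes, which are not independent replicates, was 0.297, 0.244, 0.248, 0.0621 and 0.209. Granzyme and chemokine transcripts are short, and the cytotoxic list in T cells moved from percentile 0.02 to 0.69, and in NK cells from 0.39 to 2.04, once random lists were matched on length as well as expression.

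T cells took a larger share of the named immune cells in the sitagliptin library (ratio 1.43), though not detectably of the lymphoid cells (1.08, 0.977 to 1.20). Over cells with at least 3000 UMIs the ratio was 1.33 (1.06 to 1.66). The larger share was thus not limited to T cells close to the UMI floor of the files. This cannot decide whether that floor let through more T cells of the sitagliptin library, since cells below it are absent. Barcodes holding T cell and macrophage transcripts together, more frequent in the control library, may account for the larger share. The ratio was 0.815 (0.754 to 0.881) with those barcodes counted as T cells. Such barcodes can be doublets formed in the droplets, cells joined in the tumour or macrophages with T cell RNA, and the counts do not separate these. An effect of the diet on T cell numbers stays open and untested, with 1 library per diet.

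Zbed5 and further genes were higher in the sitagliptin library across unrelated cells, Zbed5 by 51.8-fold (41.4 to 65.7) in cells with little Ptprc. Of the named higher genes measured in those cells, 8 of 12 from T cells had intervals there on the same side of 1. So had 4 of 4 from NK cells and 4 of 5 from dendritic cells. Of the named lower genes, 4 of 11, 2 of 5 and 3 of 4 had. For Zbed5, free RNA from a single cell group was argued against by its even level. Its lowest class reached 55.2% of its highest, while C1qa in T cells reached 2.02% of its level in monocytes and macrophages. This spread was not tested for the further genes. Cdk8, Il31ra and Tmem56 were among the 10 leading genes of the low-UMI cluster with 193 control and 1741 sitagliptin barcodes. In the sitagliptin library Cdk8 had 1839 CPM in monocytes and macrophages and 2708 in T cells, but Fcrls 72.6 and 0.640. More counting of short transcripts in that library was argued against by the shortest 10% of coding genes, which lay lower than the others by a log2 difference of −0.084 in monocytes and macrophages, and for Zbed5, whose 2492 nt lay between the bounds set before (1311 and 3152 nt), the argument from this opposite trend was added after its length was seen. Sequence shared with other genes covered over 20% of the 50-base words in 2 of the 12 higher genes (Eif3j1 36.9% and Polr2l 20.9%), not in Zbed5 (7.84%), against 5.92% (4.54 to 7.57) of 997 random genes. Differences between the libraries in preparation, sequencing or counting stay open beside the diet, since each diet had its own library.

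The cells with little Ptprc also had little Xist, the RNA of the inactive X chromosome (9.23 and 8.71 CPM, against 210 and 201 in monocytes and macrophages), and 4 Y-linked genes had 2 and 1 UMIs in all kept barcodes. Host stromal cells carried through the CD45 MACS enrichment, which would share the Xist of the immune cells, were argued against by an Xist level of at most 4.39% of that in monocytes and macrophages, although Dcn, Col3a1 and Col1a2 belong to the fixed fibroblast list. Cells of the injected tumour line, which that sort should also remove, may be the source, but cannot be told apart from other sources by the fixed tumour and epithelial list, since it summed to at most 0.455 CPM in these cells (8 UMIs) and 1.08 and 0.831 CPM in monocytes and macrophages. Its most abundant genes were Epcam, with 2 and 4 UMIs, and Krt19, with 2 and 1. An effect of the diet on this pattern was not tested.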
